A study of Mus musculus with 6 samples.

How the data were processed

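RNA of 6 sorted cell samples, 1 per group, was labelled with Cy3 and hybridised to 6 single-colour Agilent Mouse 60k arrays. Per the labels' protocols, mice received PBS or 200 nmol of c-di-GMP and cells were sorted 3 days later. The series text names a micro kit for RNA extraction and the labels a mini kit of the same line, and which was used is not settled here.

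Per the file headers, the deposited scanner files were made with Feature Extraction 10.7.3.1, while the submitters' processing notes name Agilent Feature Extraction 9.5.3. The deposited files give each spot's intensity, as mean, background and processed signal, with its flags. The deposited series table holds a ratio: set against the scanner values, each value is the processed signal scaled per array and divided by the probe's median over the arrays. Its column medians were 86.5 and 82.4 for HSC, 78.5 and 111 for MSC, and 107 and 139 for EC, Ctrl before cdG. Differences between its columns followed the scanner values with r of 0.999987 or more and the same direction. It holds 0 columns of other samples. The file of HSC Ctrl had been rounded and 58 of its gene name entries were altered, so names came from the HSC cdG file. Probe positions are those of mm9, per the file headers.

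Each array has 62976 spots, 59305 of them not controls, for 55681 probes. No spot was saturated. The 6 arrays share a scan start, so the scan does not separate the groups. Processed signals were log2-transformed, spots with an outlier flag were left out, spots of a probe were averaged, and the array's 75th percentile over non-control probes was subtracted. A gene was represented by the probe well above background on most of the 6 arrays, ties going to the highest mean. A gene was measured in a cell type where that probe was well above background on both arrays. Genes above background on 1 array have a bound: the bright value against the higher of the dim array's lowest signal above background and the dim probe's own signal, written as at least N-fold. Probes were named through a RefSeq gene table of assembly GRCm38.p6: 26856 by accession, 3756 by symbol and 25069 unmatched, which kept the file's name, for 35071 genes.

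With 1 array per group no test within a cell type was possible. A difference common to the 3 cell types was tested with limma, with cell type as a block, over genes measured on all 6 arrays and with Benjamini-Hochberg adjustment. This test was chosen after seeing the data. Genes were counted at a difference of at least 1 (2-fold). The 35 gene lists, the rule for named genes, the comparisons and the 7 alternatives were fixed before the data were examined. Of 739 list members, 734 had a matched gene and entered. Ahsp was measured under the file's name without a match and was left out. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays, where at least 5 members were measured. Percentiles of at least 97.5 or at most 2.5 are said to stand apart. Where a scaling moved the median gene by over 0.1, list medians are given relative to it. Series table values are centred per probe and carry no expression level, so their random lists were matched on the scanner signal. A first version matched them on the table's own means, which are no expression level, and ended more list calls under that setting. It was replaced after this was seen, with all thresholds kept.

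Named genes were, per cell type, the 12 highest and 12 lowest that were also 2-fold under normexp and quantile normalization, the 3 largest bounds each way, the 4 largest differences per list and its members above background on 1 array, a fixed set of genes, the 10 with the largest shared difference and the 5 with the largest opposite difference per pair. Names of clones and predicted genes were left out of the largest differences and bounds only. Genes named outside it were chosen after their values were seen: Hlf in HSC, Sp7, Bglap, Bglap2, Col1a1, Samd9l and Fos in MSC, Bglap, Pf4 and Mx1 in EC, and S100a9.

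The alternatives were normexp background correction (offset 50), quantile normalization, median centring of each pair, no filter on dim probes, a signal of at least 100 on both arrays, the mean over a gene's measured probes and the series table. A scaling on the 75th percentile of probes detected on all 6 arrays was chosen after seeing the data. For 3′ against 5′ probes, transcripts with probes at least 500 bases apart were used, 1792 in HSC. The order of the file's start positions matched the genome's in 1777 of 1784 of them that had coordinates.

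The steps were tested on simulated data. With 200 genes changed 4-fold and noise of the spot SD, 100% were recovered among 18439 HSC, 15336 MSC and 12356 EC genes, with 0 false genes. Such noise leaves out the variation between sorts. Of 100 random lists of 20 genes, 4%, 6% and 3% stood apart in HSC, MSC and EC, and after a shift of 1 the share was 100%, 94% and 92%. For the common fit, 200 of 10864 genes changed 4-fold were recovered at 0% with the spread between cell types that the data show, and at 100%, with 14 false genes, with a spread of 0.1. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.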

Results

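Bone marrow cells of male C57BL/6J mice aged 10 weeks were profiled on 6 single-colour arrays, 3 days after an intraperitoneal injection of PBS (Ctrl) or 200 nmol of c-di-GMP (cdG), a bacterial cyclic dinucleotide that is sensed by the receptor STING. Each of 3 sorted populations was measured on 1 Ctrl and 1 cdG array: hematopoietic stem cells (HSC), CD140a- and CD51-positive mesenchymal stromal cells (MSC) and CD31-positive endothelial cells (EC). The HSC arrays used marrow pooled from 10 mice per group. There are no replicates, so no difference within a cell type has a replicate check or a p-value. All differences are log2 values, cdG minus Ctrl, between 2 arrays.

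Signal was well above background at 51.8% of spots for HSC Ctrl and 53.6% for HSC cdG, 49.6% and 41.9% for MSC, and 38.7% and 35.3% for EC. The 75th percentile of the signal was 176 and 216 for HSC, 154 and 84.6 for MSC, and 108 and 75.6 for EC, in the same order. Probes printed 10 times had a median spot-to-spot SD between 0.0749 and 0.109 on the log2 scale. This covers the spots of 1 array and not the variation between sorts. The number of arrays limits the precision of every value.

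The level of the sorted populations' own genes was examined first, as normalized log2 signal relative to the array's 75th percentile. Cdh5, the endothelial cadherin, was at 6.47 (Ctrl) and 6.55 (cdG) in EC and was not well above background in HSC or MSC. Pdgfra, which encodes CD140a, was at 4.06 and 4.48 in MSC and was not well above background in the other 2 populations. Hlf, a transcription factor of stem cells, was at 4.89 and 4.34 in HSC and was above background with Ctrl only in MSC and EC. Among sort antigen genes in HSC, Kit was at 4.99 and 4.59, Cd34 at 4.67 and 4.07 and Ly6a at 2.77 and 2.51. Slamf1 was at -1.59 and -1.62, Cd48 at -1.08 and -1.33 and Flt3 at -0.61 and -0.33. Levels of different genes come from different probes and do not rank the genes. Sting1, which encodes STING (probe at mm9 chromosome 18, 35893692 to 35893751), was measured in all 3 populations and highest in EC, at 5.13 and 4.73, against 3.85 and 3.21 in HSC and 3.18 and 2.54 in MSC. Its difference was -0.64 in HSC, -0.64 in MSC and -0.40 in EC. Markers of other cell types were measured in the sorts as well. The osteoblast gene Bglap was at 10.09 and 9.80 in EC, the platelet chemokine gene Pf4 at 7.30 and 7.39 in EC, and the neutrophil gene S100a9 at 3.59 and 5.69 in HSC, 6.17 and 7.31 in MSC, and 7.75 and 9.40 in EC.

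The HSC comparison asked how stem cells differed after cdG. The type I interferon-stimulated genes stood out: 12 of 31 measured members were at least 2-fold higher, 0 were at least 2-fold lower and 19 lay between. Oas2, an antiviral RNA-sensing enzyme, differed by 3.04, Isg15, a ubiquitin-like modifier, by 2.25, and Irf7, a transcription factor of the interferon response, by 2.21. Mx1 and Ifit1 were well above background with cdG only, at least 26.8-fold and 10.6-fold higher. The chemokine gene Cxcl10 differed by 3.23 and led the interferon-gamma-inducible list, in which 3 of 19 members were at least 2-fold higher and 0 lower. The largest positive difference among genes measured on both HSC arrays and chosen by the fixed rule was that of Apol9b, at 4.11, and the largest negative one that of Cyp26b1, a retinoic acid-degrading enzyme, at -3.46.

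Genes of stem cell identity and of the cell cycle did not stand apart in HSC. Of 32 measured identity genes, 1 was at least 2-fold higher and 3 were lower, with Hoxb4 at 1.43, Gfi1 at -1.53, Hoxb5 at -1.48 and Procr at -1.26. Cdkn1c, a cell cycle inhibitor, was well above background with Ctrl only, at least 2.89-fold lower with cdG. Of 40 DNA replication and mitosis genes, 0 were at least 2-fold higher and 1 was lower, and Mki67 differed by 0.09. Of 19 genes of the STING sensing pathway, 0 were at least 2-fold higher or lower, with Tbk1, a kinase downstream of STING, at -0.89. Medians relative to the median gene were -0.05 (percentile 26.0 among random lists) for identity genes, 0.08 (67.1) for replication genes and 0.18 (80.0) for the STING pathway. Immediate early and heat shock genes were lower, with 5 of 23 at least 2-fold lower and 1 higher, Ier2 at -2.14, Junb at -1.71 and Hsph1 at 1.40. On the HSC Ctrl array, 9 of 21 of these genes and 29 of 32 ribosomal protein genes had their highest level of the 6 arrays. Ribosomal protein genes had 0 of 32 at least 2-fold higher or lower in HSC, with a median of -0.25 relative to the median gene (percentile 0.13). Neutrophil markers were higher, with 7 of 14 at least 2-fold higher, among them Camp at 2.69 and Ltf, the lactoferrin gene, at 2.19, and 1 lower, Prtn3 at -1.88, while Cxcr2 was above background with Ctrl only, at least 2.55-fold lower. Retnlg and Fcnb were above background with cdG only, at least 7.49-fold and 1.22-fold higher.

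In total, 909 of 18439 genes measured on both HSC arrays were at least 2-fold higher with cdG and 1119 were at least 2-fold lower. With normexp background correction these counts were 337 and 353, with a signal of at least 100 they were 325 and 433, without the filter on dim probes 2530 and 3863, and after centring on the median gene 1070 and 953, so that higher genes outnumbered lower ones. A further 1663 genes were above background with cdG only and 1197 with Ctrl only. The list medians relative to the median gene, each with its percentile among 10000 random lists matched on expression, were 0.87 (100) for type I interferon-stimulated genes, 0.59 (99.99) for interferon-gamma-inducible genes, -0.40 (0.0) for immediate early and heat shock genes and 0.99 (100) for neutrophil markers. The median gene differed by -0.07. Where a called HSC gene had other measured probes, their mean had the same sign in 72.2% of 539 genes and was at least 2-fold in 28.0%. In MSC these shares were 73.8% and 43.4% of 1250 genes, and in EC 69.0% and 43.3% of 909. The range between measured probes of 1 gene had a median of 0.57 in HSC, 0.90 in MSC and 1.01 in EC. It was over 1 in 27.0%, 46.5% and 50.3% of genes with several probes. The cdG minus Ctrl difference at a transcript's 3′ probe exceeded that at its 5′ probe by a median of 0.25 in HSC (95% bootstrap interval 0.20 to 0.29). The medians were -0.09 (-0.19 to 0.01) in MSC and -0.10 (-0.26 to 0.05) in EC. The HSC arrays thus differed in their 3′ relative to 5′ signal, which limits the HSC differences and was not corrected.

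The MSC comparison asked how the stromal niche cells differed. HSC niche factors were lower with cdG: 10 of 22 measured members were at least 2-fold lower and 3 were at least 2-fold higher. Vcam1, an adhesion molecule for stem cells, differed by -2.02, Angpt1, the ligand of Tie2, by -1.77, and the Notch ligand gene Jag1 by -1.46. In the other direction, Dkk1, a Wnt inhibitor, differed by 2.52, and Tgfb1 and Ccn3 were above background with cdG only, at least 9.56-fold and 4.96-fold higher. Kitl, which encodes stem cell factor, differed by -0.85. Cxcl12, the ligand of Cxcr4, differed by -0.38 at the probe used and by -1.15 at its other probe. Adipocyte markers were also lower, with 5 of 12 at least 2-fold lower and 2 higher, Pparg at -2.22, Adipoq at -1.57 and Scd1 at 1.56.

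Osteoblast and chondrocyte markers were higher in the same cells, with 12 of 20 at least 2-fold higher and 0 lower. Ifitm5, an osteoblast membrane protein gene, differed by 3.18, the osteoblast transcription factor gene Sp7 by 2.56 and Bglap, which encodes osteocalcin, by 1.82. Extracellular matrix genes had 16 of 38 members at least 2-fold higher and 5 lower, with the collagen gene Col1a1 at 1.75, and the laminin gene Lama5 was above background with Ctrl only, at least 22.99-fold lower. The pan-mesenchymal list moved both ways, with 6 of 25 higher and 8 lower, Dcn at 2.45 and Snai2 at -2.44. Of its 29 members 16 also belong to other lists, among them Vcam1, Kitl and Cxcl12 of the niche list and Col1a1 and Dcn of the matrix list. Its values are thus not separate from theirs. Bglap and Bglap2 are near-identical copies whose probes can share signal.

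**Figure D1:**
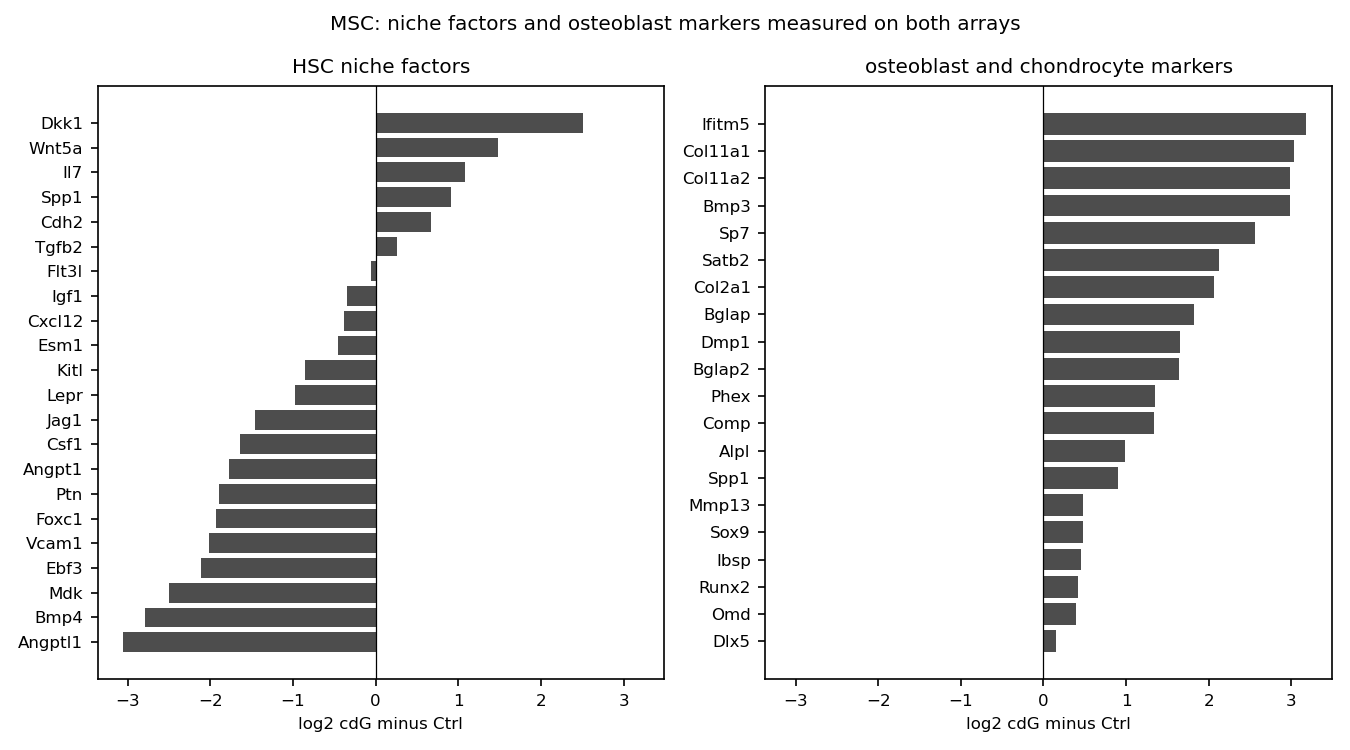
Log2 difference, cdG minus Ctrl, of each HSC niche factor and each osteoblast or chondrocyte marker measured on both MSC arrays, 1 bar per gene and 1 array per group. Of the niche factors 10 of 22 lie at or below -1, and of the osteoblast markers 12 of 20 lie at or above 1.

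Type I interferon-stimulated genes in MSC had 10 of 26 members at least 2-fold higher and 1 lower, with Irf7 and Rsad2 both at 3.30 and Samd9l at -1.77. Mx1 was above background with cdG only, at least 27.5-fold higher, and Usp18 with Ctrl only, at least 1.13-fold lower. Their median relative to the median gene was 0.37, at percentile 97.3, just inside the central 95% of random lists, and lay outside it with quantile normalization (98.1) and with the mean over a gene's probes (97.9), but further inside with normexp (95.9) and with a signal of at least 100 (89.3). DNA replication and mitosis genes were lower, with 10 of 22 at least 2-fold lower and 3 higher. A further 15 members were above background with Ctrl only and 0 with cdG only. Over all MSC genes, those above background with Ctrl only also outnumbered those with cdG only, by 3753 to 1466. Mcm3, a subunit of the replicative helicase, differed by -3.73 and Mki67 by -1.41. Immediate early and heat shock genes were higher, with 21 of 22 at least 2-fold higher and 0 lower, Egr3 at 3.52 and Fos at 1.78. Ribosomal protein genes had 17 of 32 at least 2-fold higher and 0 lower. After scaling, 99 bright probes picked for near-constant raw signal on the 6 arrays differed by a median of 0.58 in MSC. This follows from their selection, since the 75th percentiles that set the scaling were 154 and 84.6, and only 99 of 871 bright probes qualified. A 2-fold count of bright genes may thus include a shift set by the scaling, whose size this value does not give. On the MSC Ctrl array, 32 of 32 ribosomal protein genes and 18 of 21 immediate early and heat shock genes had their lowest level of the 6 arrays, so that array stood apart in genes that differed together with the groups above. Neutrophil markers were higher beside these groups, with 7 of 11 at least 2-fold higher and 0 lower, Lcn2 at 3.85 and Camp at 2.16, while Ctsg, Cd177 and Mmp8 were above background with Ctrl only, at least 5.19-fold, 3.85-fold and 1.23-fold lower. Elane and Fcnb were above background with cdG only. Erythroid markers were lower, with 5 of 12 at least 2-fold lower and 1 higher, Car1 at -3.97, and Epb42 was above background with cdG only, at least 10.03-fold higher.

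In total, 3728 of 15336 genes measured on both MSC arrays were at least 2-fold higher and 1986 lower, and 1466 and 3753 were above background with cdG only and Ctrl only. Higher and lower genes were 1859 and 1421 with normexp, 2172 and 631 with a signal of at least 100, and 8412 and 5129 without the filter. The median gene differed by 0.32, and after centring on it the counts were 2427 higher and 2764 lower, so the share of higher genes among them moved from 65.2% to 46.8%. List medians relative to the median gene, with percentiles, were -1.23 (0.0) for niche factors, -0.996 (0.02) for adipocyte markers, 1.18 (100) for osteoblast markers, 0.39 (99.4) for extracellular matrix, -0.69 (0.01) for mesenchymal markers, -0.96 (0.01) for replication genes, 1.37 (100) for immediate early genes, 0.72 (99.99) for ribosomal protein genes, 0.84 (99.2) for neutrophil markers and -1.04 (0.39) for erythroid markers. The call of the extracellular matrix list ended with the mean over a gene's probes, at percentile 86.3.

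The EC comparison asked the same of endothelial cells. Interferon-stimulated genes were higher: 19 of 24 measured members were at least 2-fold higher and 0 were at least 2-fold lower. Rsad2, an antiviral enzyme, differed by 7.71, Ifit3 by 5.05 and Isg15 by 4.54. Oasl1, Usp18 and Ifih1 were above background with cdG only, at least 29.3-fold, 14.5-fold and 9.93-fold higher, and Oas1a with Ctrl only, at least 2.01-fold lower. Mx1 was not well above background on either EC array. Ifit3 and its copy Ifit3b can share probe signal.

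**Figure D2:**
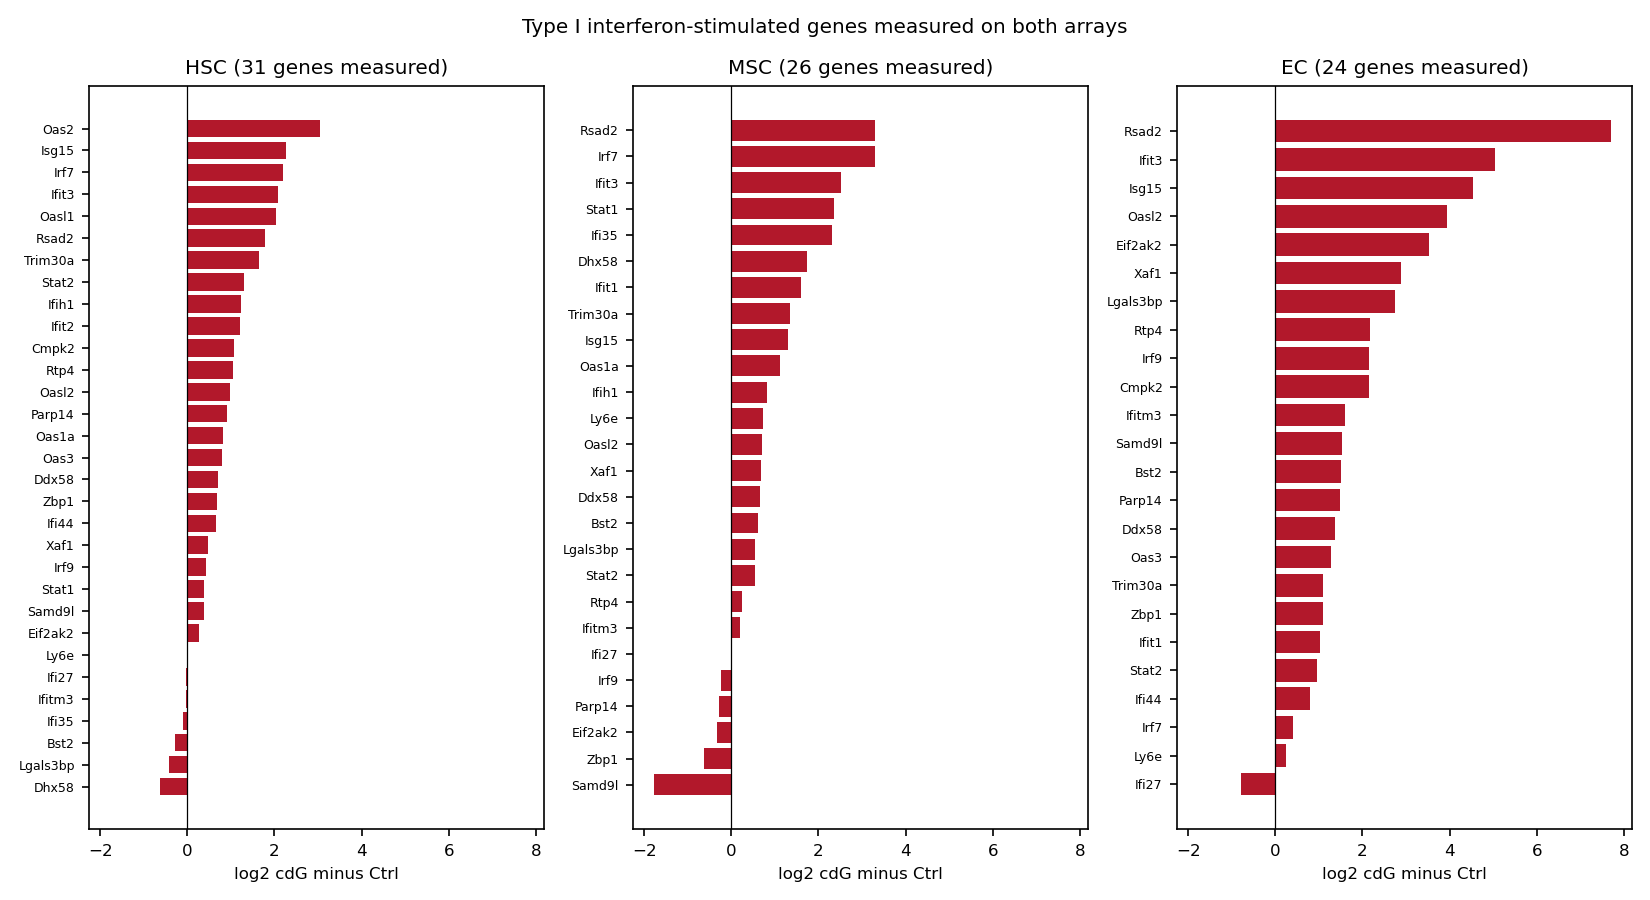
Log2 difference, cdG minus Ctrl, of each type I interferon-stimulated gene measured on both arrays of a cell type, 1 bar per gene and 1 array per group. At least 2-fold higher were 12 of 31 genes in HSC, 10 of 26 in MSC and 19 of 24 in EC.

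Endothelial markers moved both ways in EC, with 10 of 34 at least 2-fold higher and 5 lower, and Cdh5 differed by 0.08, which is -0.24 relative to the median gene. The sort antigen list pools the antigens of all 3 sorts and is not that of the EC gate alone. In EC 6 of its 7 measured members were at least 2-fold higher. Among them were Pecam1, which encodes CD31, at 3.58, and Cd34 at 4.01 at the probe used and 0.99 at its other probe. The sort antigen genes Cd48 and Ptprc, which encodes CD45, were above background with Ctrl only, at least 5.46-fold and 1.32-fold lower. Angiogenesis, Notch and Hippo target genes had 9 of 23 members at least 2-fold higher and 2 lower and did not stand apart. Angpt2, a Tie2 ligand, differed by 4.76 and Vegfa by -2.27 at the probe used and 0.26 at its other probe, and Apln and Pgf were above background with cdG only, at least 547-fold and 427-fold higher. Niche factors moved both ways, with 5 of 16 higher and 3 lower, Angpt1 at -2.29, Vcam1 at -1.50, Kitl at 0.84 and Cxcl12 at -0.75. The inflammatory list had 5 of 14 members higher and 6 lower, with Ccl2, a monocyte chemoattractant, at 6.54 and Cxcl5 at -3.75. Of 15 genes of the STING sensing pathway, 3 were higher and 4 lower, with the interferon receptor gene Ifnar1 at -3.70 at the probe used and -0.26 at its other probe. Neutrophil markers had 12 of 17 members higher and 2 lower, with Ngp at 4.11, and Cebpe and Fcnb were above background with cdG only.

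In total, 2937 of 12356 genes measured on both EC arrays were at least 2-fold higher and 1893 lower, and 2101 and 3284 were above background with cdG only and Ctrl only. Higher and lower genes were 1862 and 1593 with normexp, 1778 and 923 with a signal of at least 100, and 7741 and 5384 without the filter. The median gene differed by 0.32, and centring on it gave 2105 higher and 2465 lower, a share of higher genes of 46.1% against 60.8%. List medians relative to the median gene, with percentiles, were 1.20 (100) for interferon-stimulated genes, -0.16 (19.6) for endothelial markers, 2.34 (99.96) for sort antigens, 0.11 (71.6) for niche factors, 0.27 (91.6) for angiogenesis genes, -1.03 (0.85) for the inflammatory list, -0.89 (2.42) for the STING pathway and 1.33 (100) for neutrophil markers. The inflammatory and STING lists no longer stood apart without the filter on dim probes, at percentiles 27.0 and 5.33, and the STING list not with a signal of at least 100 or the mean over a gene's probes (5.30) either.

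**Figure D3:**
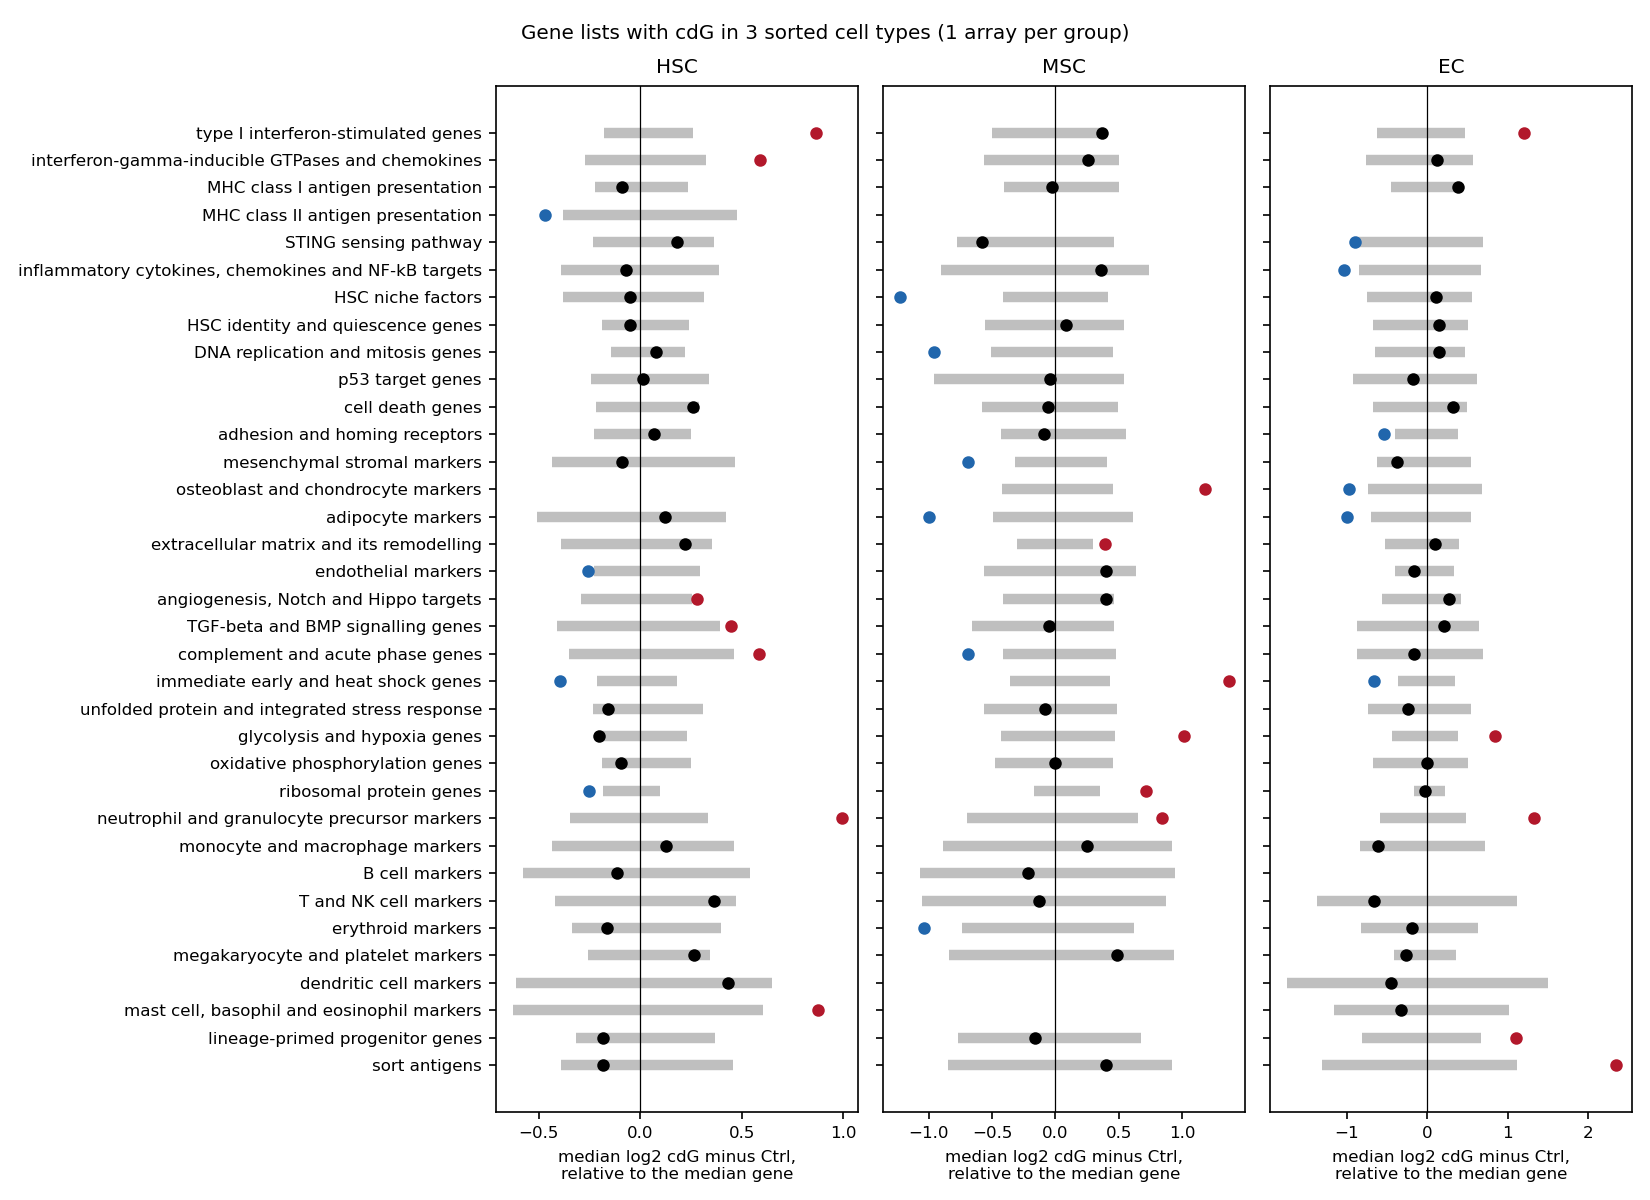
Median log2 difference of each gene list relative to the median gene of that comparison (points) and the central 95% of 10000 random lists matched on expression (grey bars), for HSC, MSC and EC with 1 array per group. Red points lie above that central part and blue points below it, in 18 and 16 of 99 list comparisons.

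The differences of the 3 populations were compared across the 10864 genes measured on all 6 arrays. Pearson's r across genes, which are not independent replicates, was -0.08 between HSC and MSC, -0.03 between HSC and EC and 0.06 between MSC and EC, and Spearman's rho was -0.12, -0.04 and 0.05. At least 2-fold higher in all 3 were 33 genes, against 17.8 in independent lists, and 18 were at least 2-fold lower, against 5.27. These counts were 16 (against 2.80) and 7 (1.62) with normexp, 17 (5.38) and 2 (0.58) with a signal of at least 100, 187 (134) and 148 (86.7) without the filter, and 21 (7.87) and 20 (9.15) with the percentile of detected probes. Between HSC and MSC, 91 genes were higher in both, against 77.7 in independent lists, 52 lower in both, against 37.8, and 166 opposite. Between HSC and EC these were 98 (81.7), 59 (47.6) and 182, and between MSC and EC 585 (544), 296 (168) and 655. No count of opposite genes in independent lists was computed. The counts thus do not part a shared direction from genes that vary either way. Of the 33 higher genes, 5 belong to the interferon lists and 7 to the neutrophil list. The 10 with the largest difference in the population where it was smallest were Ifit3, Ifit3b, Rsad2, Camp, Ltf, Ngp, Lcn2 and the predicted gene Gm10847, higher in all 3, and Blvra and Ripply3, lower in all 3. Ltf, an iron-binding granule protein gene, differed by 2.19 in HSC, 2.24 in MSC and 2.94 in EC. Blvra, which encodes biliverdin reductase A, differed by -2.69, -3.55 and -1.75, and its other probe by -0.80, -0.01 and 1.60. A limma fit of cdG with cell type as a block, on 2 residual degrees of freedom, found 0 of 10864 genes with a common difference at an adjusted p under 0.05, and 396 at an unadjusted p under 0.05, where chance gives 543. Camp had the smallest p in that fit, with a mean difference of 2.42 and higher in 3 of 3 populations (limma adjusted p = 0.913). On simulated data with the fitted spread, this fit recovered 0% of genes changed 4-fold. The SD of differences over genes was 0.65 in HSC, 1.22 in MSC and 1.44 in EC, and 0.43, 0.83 and 0.84 among the brightest 20% of genes.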

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

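All tests of explanations in this part were chosen after the results were seen, and no difference between cell types was tested, since each group is 1 array. Effects that moved opposite ways in 2 cell types are given first. Values for lists are medians relative to the median gene. What is said of scaling rests on quantile normalization and normexp, since the other scalings shift all genes of a pair alike and cannot move a list's percentile. Random lists come from the same arrays at matched levels, so a shift common to genes of similar level largely cancels. The percentiles thus show whether a call depends on the scaling, and do not test scaling as a cause.

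Immediate early and heat shock genes were at 1.37 in MSC, against -0.40 in HSC and -0.66 in EC. The list stood apart in MSC under quantile normalization and normexp as well, with a lowest percentile of 100, so its call did not depend on these scalings. The MSC Ctrl array had the lowest level of the 6 for 18 of 21 members, as a control array that stands apart would give, and the HSC Ctrl array had the highest for 9 of 21. Handling before extraction, which may alter 21 of 22 members at once, cannot be told apart from treatment, because each group had 1 sort. An effect of cdG stays open as well, untested.

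Osteoblast and chondrocyte markers were at 1.18 in MSC against -0.97 in EC, where the list no longer stood apart with normexp (percentile 2.68). In MSC the niche factors stood apart under quantile normalization and normexp as well, with a highest percentile of 0.0, so their call did not depend on these scalings. The osteoblast markers were at percentile 100 among random lists of the same 2 arrays, so their median lay above those of random genes at matched levels. This is the value by which the list stood apart among 99 comparisons, so it is no separate test of independent scatter of single genes. Another mix of stromal cells in the sort could give the same values: the osteoblast differences had an SD of 1.01, and no scatter between arrays of 1 group is known to set it against. A response of the stromal cells to cdG stays open, untested.

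Complement and acute phase genes were at 0.58 in HSC against -0.69 in MSC. Ribosomal protein genes were at 0.72 in MSC against -0.25 in HSC, with their lowest level of the 6 arrays on the MSC Ctrl array for 32 of 32 and their highest on the HSC Ctrl array for 29 of 32.

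Between HSC and MSC, a transcribed region on chromosome 7 differed by -2.69 and 3.38, and by -0.27 at another of its probes in HSC. Zswim6 differed by -2.61 and 2.83, and its other probes reached 0.54 and -0.69. Eif2b5 differed by -2.52 and 2.62. A region on chromosome 17 differed by -2.93 and 2.42. Sesn2 differed by 2.43 and -2.41. Between HSC and EC, Wtip differed by -2.52 and 3.09. A probe without a gene name was at 2.42 and -3.04. A region on chromosome 8 was at 2.68 and -2.42. Ramp3 was at -2.41 and 4.99. A region on chromosome 16 was at 2.41 and -2.39. Between MSC and EC, the transcript C130045F17Rik was at 6.32 and -4.07. Pdcd2 was at -3.95 and 6.30. Galt was at 4.04 and -3.88. A region on chromosome 4 was at 3.98 and -3.87, and at -0.43 at another of its probes in MSC. Nhsl2 was at -5.10 and 3.74, and its other probes reached 1.38 and -1.65.

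The limma fit over the 3 cell types gave 0 genes at an adjusted p under 0.05, and the highest of the other splits gave 0. At an unadjusted p under 0.05 it gave 396, and the other 9 splits gave 13 to 1940, with 5 above 396. Of these 9, 3 part the arrays of each cell type as treatment does and gave 337 to 585, while the other 6 part those of 1 cell type only. The 10 splits of the 6 arrays are too few for a share under 0.05.

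The neutrophil markers, of which 7 also belong to another list, were higher with cdG in all 3 populations. Their percentile was at least 99.21 in each under quantile normalization and normexp, so the call did not depend on these scalings. A lower share of the sorted cells would raise other blood cell markers alike, and against these markers pooled the neutrophil median was higher by 1.67 in EC (95% bootstrap interval over genes 0.99 to 2.18), by 0.82 in HSC (-0.65 to 2.11) and by 0.92 in MSC (-0.10 to 2.21). A test of each list by itself, with intervals adjusted over the lists, replaced the pooled one after the values were seen. In MSC the interval lay above 0 only against erythroid markers, at 1.88 (0.25 to 4.10), a list that was itself lower there (-1.04). In EC it did so against monocyte and macrophage markers, at 1.93 (0.30 to 3.29), and megakaryocyte and platelet markers, at 1.59 (0.22 to 2.38). The intervals of the other 4 lists in MSC and of 2 of 4 in EC reached 0. All 5 in HSC did, with B cell markers at 1.11 (-0.60 to 3.55). These intervals cover genes of 1 array pair and not the variation between sorts. With the pooled interval, this argues against a lower share that raises these markers alike in EC, and leaves it open in HSC and MSC. Granulocytes or their RNA in each sort are a candidate source, since the signal increments of 10 members kept a similar order, with a lowest Spearman's rho of 0.83 between 2 cell types, and S100a9 reached 9.40 in EC, although the gates exclude CD45-positive cells from MSC and EC and take LSK cells, which are lineage-negative, for HSC. Ptprc, which encodes CD45, was at -0.84 in HSC. It was above background with Ctrl only in MSC and EC, at least 1.05-fold and 1.32-fold lower. These values do not decide it, since the HSC gate as given here does not exclude CD45 and the bounds in MSC and EC were small. There, genes with Ctrl only outnumbered those with cdG only in general, by 3753 to 1466 and 3284 to 2101. In MSC, Ctsg, Cd177 and Mmp8 were above background with Ctrl only, and Elane and Fcnb with cdG only, as Fcnb was in HSC and EC. Since a proportional response in each population would give the same order, granulocytes and such a response cannot be told apart.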

How the results depend on the processing

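The 75th percentile over probes detected on all 6 arrays was chosen after seeing the data. The labels carry no replicate numbers. No paired analysis was possible within a cell type because each group holds 1 array, and for the same reason there is no MSC count without the MSC Ctrl array. A paired fit over the 3 cell types, chosen after seeing the data, gave 0 genes at an adjusted p under 0.05 with limma in the main and all 8 other settings, with a smallest adjusted p of 0.897 over these settings and 0.913 in the main one. At an unadjusted p under 0.05 it gave between 267 of 6405 genes, with a signal of at least 100, and 1262 of 35070, without the filter. On simulated data with the fitted spread it recovered 0% of genes changed 4-fold, so its count of 0 does not show that no such gene exists. Of 34 list comparisons that stood apart, 23 did so under all 8 alternatives. Of these, median centring and the percentile of detected probes shift all genes of a pair alike and cannot alter a list's percentile, and the series table repeats the scanner values (r of 0.999987 or more), so 5 were tests of the lists. No list that stood apart and no named gene with at least a 2-fold difference turned its sign. For named genes this was largely set beforehand. Those with the largest differences were chosen to be 2-fold under normexp and quantile normalization as well. The filter settings and the series table repeat the values, and the probe mean includes the chosen probe. The mean of a called gene's other measured probes had the same sign in 72.2% of genes in HSC. In MSC and EC these shares were 73.8% and 69.0%. The balance of higher and lower genes did turn: median centring gave 1070 and 953 in HSC, 2427 and 2764 in MSC and 2105 and 2465 in EC, and the percentile of detected probes 2239 and 2903 in MSC and 2130 and 2435 in EC. The signal over background limits all counts, since dim genes make up many of them. The causes of the changes below were not tested, except that a filter changes which genes enter.

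With normexp, higher and lower genes were 337 and 353 in HSC, and higher genes 1859 in MSC and 1862 in EC, with 16 higher and 7 lower in all 3 and r of -0.10 between HSC and MSC. The percentile of detected probes gave 21 higher in all 3. Without the filter the counts were 2530 and 3863 in HSC, 8412 and 5129 in MSC, 7741 and 5384 in EC, and 187 and 148 in all 3, with r of -0.0552 between HSC and MSC and -0.00778 between HSC and EC. With a signal of at least 100 they were 325 and 433, 2172 and 631, 1778 and 923, and 17 and 2, with r of -0.14 between HSC and MSC and 0.0340 between MSC and EC.

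List medians relative to the median gene are given where the list entered or left the central 95% of random lists. With normexp, EC osteoblast markers (-0.65) and HSC TGF-beta genes (0.18) no longer stood apart. With quantile normalization, MSC type I interferon-stimulated genes (0.34) and MSC angiogenesis genes (0.30), inside the central part in the main setting, stood apart. Without the filter, EC STING pathway (-0.90), inflammatory (-0.0855), adhesion (-0.62), adipocyte (-0.75) and lineage-primed genes (0.17) and HSC endothelial (-0.0573) and mast cell, basophil and eosinophil markers (0.11) no longer stood apart, while EC MHC class I (0.29), MSC B cell (0.39, against -0.22 with the filter), HSC T and NK cell (0.44) and HSC megakaryocyte markers (0.53) did. With a signal of at least 100, EC STING pathway (-0.92) and lineage-primed genes (0.47) and HSC endothelial (-0.20) and angiogenesis genes (0.29) no longer did, while MSC angiogenesis (0.47) and HSC megakaryocyte genes (0.48) did. With the mean over a gene's probes, EC STING pathway (-0.70) and adhesion genes (-0.39), MSC extracellular matrix (0.17) and HSC angiogenesis genes (0.19) no longer did, while MSC type I interferon-stimulated genes (0.38) and HSC megakaryocyte markers (0.48) did. Over all settings, 756 values of lists kept their side of the threshold. Of these, 99 each came with median centring, the percentile of detected probes and the series table, which cannot move a list or repeat the scanner values. Of named genes, 1493 values moved by more than the spot SD of a difference and 2368 did not. The filter settings keep the same values and the series table repeats them. Their 511 values without the filter, 284 with a signal of at least 100 and 511 with the series table thus could not show stability. With normexp 425 moved and 86 did not, and with quantile normalization 303 and 208.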

Other observations

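All groups of genes below were fixed in advance. Values for lists are medians relative to the median gene, with percentiles among random lists, and no list was tested for a difference.

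Glycolysis and hypoxia genes were higher with cdG in both niche populations. The MSC Ctrl array had the lowest level of the 6 for 9 of the 17 members measured on all 6, and the EC cdG array the highest for 11 of 17. In MSC 13 of 19 measured members were at least 2-fold higher and 1 was lower (1.01, percentile 99.995), with Adm, a vasodilator peptide gene, at 2.92, Hk2 at 2.25 and the lactate transporter gene Slc16a3 at -2.21. In EC 11 of 20 were higher and 3 lower (0.85, percentile 100), with Pfkl at 4.07 and Vegfa at -2.27 at the probe used and 0.26 at its other probe. In HSC 1 of 22 was higher and 2 were lower (-0.20, percentile 2.77). Adipocyte markers were lower in EC as in MSC, with 5 of 12 at least 2-fold lower and 1 higher (-0.99, percentile 0.40), but the EC list no longer stood apart without the filter on dim probes (percentile 3.93), where the MSC list did (0.03). Complement and acute phase genes in MSC had 4 of 18 members higher and 4 lower, Saa3 at 2.91 and C1s1 at -2.06.

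Markers of mast cells, basophils and eosinophils moved both ways in EC. The eosinophil granule gene Prg2 differed by 6.12, and Epx was above background with cdG only, at least 57.3-fold higher. The basophil protease gene Prss34 differed by -4.18, and Mcpt8 was above background with Ctrl only, at least 44.6-fold lower. In HSC this list had 2 of 5 members higher and 1 lower, Gata1 at 1.93 and Cpa3 at -2.44, and stood apart with the filter on dim probes (percentile 99.59) and not without it (82.0). Among HSC, 4 of 22 endothelial markers were at least 2-fold lower and 0 higher, Emcn at -1.86, a list that stood apart (percentile 1.26) but not without the filter (7.61) or with a signal of at least 100 (3.78), and the MHC class II invariant chain gene Cd74 differed by -1.92. Angiogenesis, Notch and Hippo target genes had 6 of 16 members higher and 0 lower in HSC, Angpt2 at 1.21 and Notch1 at 1.12 at the probe used and -0.74 at its other probe. This list stood apart in HSC (percentile 98.3) but not with a signal of at least 100 (94.8) or the mean over a gene's probes (92.3).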
